A study of Homo sapiens with 16 samples.

How the data were processed

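Primary lung fibroblasts were grown out of minced lung tissue and used at or before passage 4, per the labels' protocols. They came from 4 donors with idiopathic pulmonary fibrosis (IPF) and 4 control donors. Per the labels' protocols, small cells were sorted by flow cytometry on the surface glycolipid SSEA4. SSEA1 is named in the gate too, but the label text does not show whether cells with or without it were kept. Part of the sorted cells gave the day 0 libraries, and their progeny, grown for 21 days from 100 sorted cells per well, gave the day 21 libraries. Each donor has 1 library at each day, so the 16 libraries form 4 groups of 4. Libraries were made from oligo-dT selected RNA, per the labels' protocols.

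The submitters' processing notes name FastQC, TopHat2 2.0.8 and hg19. The tool that counted reads, the filter on low genes and the transformation are not given in the sources used here. The deposited values are on a log scale, one value for each of 13620 genes named by Entrez gene ID, and the base is taken as log2, an assumption, because 2 to the power of the values sums to a total of the size of a sequencing library. The deposited values were quantile normalized by the submitters over the 16 samples. In a check of the sorted columns, 99.894% of values lay within 0.05 of the median column. Quantile normalization gives every library the same distribution, so a change in total RNA cannot be seen, and the gene with the highest value in every library cannot change. Read totals are not given in the sources used here, so the depth of each library is unknown and no interval from counting error is given. Values ran from 3.498 to 19.81 on the log2 scale.

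Gene symbols were taken from the RefSeq annotation of GRCh38.p14 by Entrez ID, and 13560 of the IDs matched while 60 did not. Only names were used, not coordinates, since the alignment was to hg19. Y-linked genes, XIST and TSIX were removed from all tests. Because the scale of the values is not stated, genes were kept when their mean over the 16 libraries was above the 25th percentile of all genes (8.5032), which left 10209 genes. The stricter alternative kept 8398.

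Comparisons were IPF against control at day 0 and at day 21 (8 libraries each), day 21 against day 0 in control and in IPF (8 libraries each), and the difference between these changes (the interaction of disease and day, 16 libraries). A sixth comparison, day 21 against day 0 over all 8 donors with disease as a covariate, was added after the results of the other 5 had been seen. Each was fitted with limma 3.58.1 (R 4.3.3) with a mean-variance trend on the values, and p values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of adjusted p under 0.05. The donor was not a term in these fits. It was used as a block in an alternative, because the labels' titles give the same donor at both days. In a check of the pairing, deviations from the group means were compared between the libraries of a donor. Pearson's r across genes, which are not independent replicates, ran from 0.003 to 0.539 over the 8 donors, with a median of 0.265. It was above 0.1 in 6 of 8, and in 5 of 8 the donor's own library gave the highest r.

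Gene lists, the tests, the low value filter and the rule for naming genes were fixed before the data were examined. Of 34 lists, 25 had at least 5 tested genes. These were tested with camera (limma) at a preset correlation between genes of 0.01, with Benjamini-Hochberg over the 25 lists in each comparison, and again with an estimated correlation. The mean of each list per library was also compared between donors by exact two-sided permutation tests, of the disease labels for differences between diseases and of the signs of the donors' changes for changes with time. These donor-level tests, and 5 further lists written after the leading genes had been seen, were added later, and the further lists were tested without the genes that led to them. ASNS and CHAC1, which are in 2 lists, were kept in that of amino acid supply, which was also tested without them.

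Named genes are, for each comparison, the 10 rising and 10 falling genes with the largest log2 fold change among those past the threshold whose direction holds in every donor. For the differences between diseases, the groups were not to overlap instead. Where fewer than 5 qualified in a direction, the 5 with the smallest p were taken. Up to 3 members with the smallest p were added for each list described, and further members that passed were named after their values had been seen. ST3GAL1, ST3GAL2, S100A4, COL1A1, COL3A1, ACTA2, MKI67 and FN1 were followed in every comparison. Long non-coding and uncharacterized loci other than list members, pseudogenes, HLA genes, antigen receptor segments, and genes with common deletions or escape from X inactivation were tested but not named.

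The alternatives were no filter, a stricter filter, quantile normalization repeated on the genes tested, cyclic loess normalization, no mean-variance trend, sample weights, a minimum log2 fold change of 1, the donor as a block, all 16 libraries with the donor as a random effect, and the series of sample names as a covariate. Each donor was also left out in turn, and 1 outlying library was left out alone. The fits were tested on simulated data with the spread of these libraries, 200 changed genes and groups of the same size. Noise was drawn independently for each gene and library, without correlation between genes, deviations shared by a donor's libraries or an outlying library. The shares recovered hold for that setting. They do not show that changes of these sizes are absent where no gene passed. Changes of 2 on the log2 scale were recovered in 93% of cases for IPF against control at day 0 and 89% at day 21. The share was 95% for day 21 against day 0 in control, 83% in IPF, 79% for the interaction and 99% over all donors. For changes of 1 the shares were 61%, 54%, 69%, 37%, 44% and 77% in the same order. Some of the genes past the threshold are not reported here. Principal components were computed on the tested genes, centred per gene. Tables and plots were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.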

Results

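RNA was sequenced from 16 libraries of human lung fibroblasts, and the study's title places them in the search for a cell of origin of the fibroblasts that fill the fibrotic lung. The groups were control day 0, control day 21, IPF day 0 and IPF day 21, each with 4 donors and 1 library per donor. Day 0 cells were small SSEA4-sorted cells and day 21 cells were their progeny in culture. The measure was the normalized expression of each gene on a log2 scale. The depth of the libraries is unknown. Changes are log2 fold changes ± the standard error from limma, with Benjamini-Hochberg adjusted p over 10209 genes. Genes are given by symbol, with the Entrez ID of the leading ones, and positions were not used here.

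The first question was which genes change between the sorted cells and their progeny in control donors. FGL2, A2M and IGFBP5 were among the genes that rose, and TGF-beta response genes such as PMEPA1 and TNFAIP6 fell. FGL2 (Entrez 10875), which encodes a secreted fibrinogen-like protein, rose by 4.52 ± 0.74 (n = 4 donors, adjusted p = 0.0271). CEMIP (Entrez 57214), which degrades hyaluronan, rose by 3.23 ± 0.50 (adjusted p = 0.0262), and the protease inhibitor gene A2M (Entrez 2) by 2.88 ± 0.32 (adjusted p = 0.0140). IGFBP5, RGCC, RASSF2, SLC16A6, IRAG1, FAM43A and DEPP1 rose by 2.64 to 3.21. The heme oxygenase gene HMOX1 (Entrez 3162) fell by 3.13 ± 0.55 (adjusted p = 0.0352) and PMEPA1 (Entrez 56937), a feedback inhibitor of TGF-beta signalling, fell by 2.40 ± 0.30 (adjusted p = 0.0152). AMIGO2, LMO4, GFPT2, TNFAIP6, COL7A1 and ADAM12 had changes from −1.89 to −3.02 and passed as well. ADAMTS6, a matrix protease gene, fell by 2.01 ± 0.44 (adjusted p = 0.0499, and 0.0525 with the donor as a block). Each of these genes went the same way in 4 of 4 control donors.

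In all, 257 genes passed in control, 151 up and 106 down, and 2681 had an unadjusted p under 0.05 where chance gives 510. With the donor as a block 586 passed, 368 up and 218 down, and 230 genes were in both sets. With 3 donors the count was 0 without replicate 2, 16 without replicate 1, 7 without replicate 4 and 433 without replicate 3, while the changes kept their size: A2M rose by 2.62 to 3.10, CEMIP by 3.14 to 3.35 and FGL2 by 4.00 to 4.96, and PMEPA1 was at −2.20 to −2.57. Of the named genes none passed without replicate 2 (A2M 0.124, PMEPA1 0.157), only A2M, PMEPA1 and COL7A1 passed without replicate 1 (0.0522 to 0.159 for the rest), and only A2M and LMO4 without replicate 4 (0.0808 to 0.143). Without replicate 3 IGFBP5, IRAG1, HMOX1, AMIGO2, GFPT2, TNFAIP6 and ADAM12 did not pass (0.0505 to 0.0802). GFPT2, ADAMTS6 and TNFAIP6 were also just short of the threshold with no filter (0.0532, 0.0546 and 0.0507) and under cyclic loess normalization (0.0505, 0.0518 and 0.0512), as were AMIGO2 (0.0504) and ADAM12 (0.0516) with no filter, and GFPT2 (0.0512) and ADAMTS6 (0.0522) without the mean-variance trend.

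Gene lists by function were also tested in control donors. The TGF-beta list holds PMEPA1 and TNFAIP6, so it is not independent of the genes named above. All 17 tested genes of the TGF-beta response, the program that fibroblasts run when this cytokine activates them, had negative changes (camera adjusted p = 8.01e-06, and 0.453 with an estimated correlation). PMEPA1, BHLHE40 (−1.43 ± 0.28), TNFAIP6 and SKIL (−1.83) fell, which makes 4 genes over all genes and 10 adjusted over the list alone. Genes of the unfolded protein response, which meets the load of proteins in the endoplasmic reticulum, were lower in 18 of 20 cases (adjusted p = 3.11e-05, and 0.598 with an estimated correlation). The chaperone genes HYOU1 (−1.32 ± 0.21) and SDF2L1 (−1.33 ± 0.22) fell, and MANF fell by 1.20 ± 0.26 (adjusted p = 0.0488, and 0.0609 with the donor as a block). That is 3 genes over all genes and 11 adjusted over the list alone. All 20 mitosis genes and all 20 DNA replication genes had negative changes (adjusted p = 3.82e-05 for each, and 0.658 with an estimated correlation). Of these the kinase gene AURKB (−1.23 ± 0.23) fell over all genes, and 3 mitosis and 12 replication genes passed adjusted over the list alone, among them FEN1 (−0.86 ± 0.25). The mean of the DNA replication list rose in control replicate 3 (0.215).

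Interferon response genes were higher in 7 of 8 cases in control (adjusted p = 0.00106, and 0.453 with an estimated correlation). Past the threshold were 1 member over all genes and 4 adjusted over the list alone, XAF1 (0.87 ± 0.31) among the 4. Of the p53 targets 16 of 17 were positive (adjusted p = 0.00106, and 0.658 with an estimated correlation), with 0 members past the threshold in limma either way. The list's call was lost without replicate 2 (0.0966). Contractile genes were up as a list (adjusted p = 0.0364, and 0.658 with an estimated correlation), with the myosin kinase gene MYLK up by 1.25 ± 0.20 over all genes and 5 up and 1 down adjusted over the list alone. This call was lost without replicate 4 (0.198) and under cyclic loess normalization (0.0522). The BMP pathway was down (adjusted p = 0.0364, and 0.658 with an estimated correlation), with 0 genes over all genes and 3 adjusted over the list alone, namely FSTL3 (−2.43 ± 0.62), ID3 (−2.99 ± 0.79) and ID4 (−2.05). It was lost without replicate 1 (0.121) or 2 (0.0781). Lung mesenchyme transcription factors were up (adjusted p = 0.0459, and 0.453 with an estimated correlation), led by NR2F2 (0.76 ± 0.14), with 1 gene up over all genes and 6 up and 1 down adjusted over the list alone. Their call was lost without replicate 2 (0.0873) or 3 (0.0671) and under cyclic loess normalization (0.0532). Cholesterol synthesis genes were lower in 16 of 20 cases (adjusted p = 0.0459, 0.0746 with the donor as a block and 0.920 with an estimated correlation), and the call was lost without replicate 3 (0.835) or 4 (0.846). The control donors did not share a direction. The list mean rose in replicates 1 (0.401) and 2 (0.412) and fell in replicates 3 (−1.127) and 4 (−1.223).

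The same question in IPF donors gave 3 genes, all up. GABARAPL1 (Entrez 23710), which acts in the formation of autophagosomes, rose by 2.61 ± 0.22 (n = 4 donors, adjusted p = 0.0135, and 0.0417 with the donor as a block). The glycogen regulator gene PPP1R3C (Entrez 5507) rose by 2.75 ± 0.29 and ARHGEF25 (Entrez 115557) by 1.13 ± 0.12 (adjusted p = 0.0384 for each, and 0.0920 and 0.0950 with the donor as a block). All 3 were higher in 4 of 4 donors. With the block SEMA7A (−3.27 ± 0.20) and RGCC (1.91 ± 0.12) passed beside GABARAPL1 (adjusted p = 0.0417 for each). Short of the threshold were PLTP (1.51 ± 0.19) and DOCK10 (−0.91 ± 0.11, adjusted p = 0.0598 for both), PODXL (−3.70 ± 0.49, adjusted p = 0.0687), and PCDH18 (1.61 ± 0.22), SIPA1L3 (−1.14 ± 0.16), PSD4 (−1.86 ± 0.28) and PPP1R14B (−1.07 ± 0.16), each with an adjusted p of 0.0725. At an unadjusted p under 0.05 there were 2010 genes, 918 up and 1092 down. With sample weights 37 genes passed, 24 up and 13 down. The count was 0 without replicate 1, 3 or 4 or without the day 21 library of replicate 3 alone, and 2 without replicate 2. With 1 donor left out the changes stayed at 2.54 to 2.73 for GABARAPL1, 2.56 to 2.95 for PPP1R3C and 1.03 to 1.22 for ARHGEF25. GABARAPL1 lost its call without replicate 1 (0.166), 3 (0.0664) or 4 (0.373). PPP1R3C and ARHGEF25 lost theirs without any 1 of the 4 donors, and ARHGEF25 also without the mean-variance trend (0.0511).

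Among the lists in IPF donors, p53 targets were higher in 15 of 17 cases (camera adjusted p = 2.21e-04, and 0.893 with an estimated correlation), with ZMAT3 at 0.88 ± 0.22 and TP53INP1 at 1.47 ± 0.44. Unfolded protein response genes were higher in 19 of 20 cases (adjusted p = 0.00203, and 0.893 with an estimated correlation), led by the transcription factor gene XBP1 (0.77 ± 0.23) and the asparagine synthetase gene ASNS (1.46 ± 0.44). All 8 interferon genes were positive (adjusted p = 0.00301, and 0.893 with an estimated correlation), and IFI6 (1.71 ± 0.36) and XAF1 (1.52 ± 0.36) passed adjusted over the list alone, against 0 over all genes. All 20 DNA replication genes and all 20 cholesterol synthesis genes were negative (adjusted p = 0.00301 and 0.0361, and 0.893 for both with an estimated correlation), among them CDC6 (−1.21 ± 0.54) and ACAT2 (−1.24 ± 0.36). In each of these lists except interferon, 0 members passed limma over all genes or adjusted over the list alone. Without replicate 3 the calls were lost for the unfolded protein response (0.0662) and DNA replication (0.298), the latter also without the day 21 library of that donor alone (0.110). The interferon call was lost without replicate 1 (0.181) and the cholesterol call without replicate 1 (0.193) or 2 (0.205). The mean of the cholesterol list rose in replicate 3 (0.42), and its change was −0.57 with all IPF donors and −0.89 without replicate 3. Mitosis and lung mesenchyme transcription factors had an adjusted p of 0.0609 each, and passed with the donor as a block (0.0261 and 0.0445). Neither passed with an estimated correlation. The mean of the mitosis list changed by −1.09 with all IPF donors and by −0.09 without replicate 3. The 5 lists past the threshold became 8 without replicate 2. The TGF-beta response did not pass (0.0871).

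Over all genes the changes in control and in IPF were alike in direction. Pearson's r across genes, which are not independent replicates, was 0.693, and 0.571 without IPF replicate 3. Of the 257 genes past the threshold in control, 239 (93%) had the same sign in IPF, against 74.62% of all genes, and 118 also had an unadjusted p under 0.05 in IPF. The genes that rose in control had a median change of 1.17 there and 0.91 in IPF, and those that fell had −0.91 and −0.71. Both lists of called genes shared 2 genes, PPP1R3C and ARHGEF25, where independent lists would share 0.0755.

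Day 21 was therefore also compared with day 0 over all 8 donors. In this added comparison FGL2 rose by 3.92 ± 0.73 (n = 8 donors, adjusted p = 0.00395), the lipid carrier gene APOE (Entrez 348) by 3.48 ± 0.70 (adjusted p = 0.00537) and the collagen gene COL14A1 (Entrez 7373), whose product binds fibrils, by 3.07 ± 0.53 (adjusted p = 0.00285). PTGDS, MASP1, A2M, BDKRB2, ALDH1A1, FBLN1 and PODN rose by 2.68 to 3.23, with FBLN1 (Entrez 2192), an elastic fibre gene, at the smallest adjusted p of the genes named by size (8.55e-04). PODXL (Entrez 5420), a sialomucin gene of cell surfaces, fell by 3.29 ± 0.48 (adjusted p = 0.00164) and SEMA7A by 2.82 ± 0.47 (adjusted p = 0.00233). SPHK1, HMOX1, PCDH9, ADAMTS6, HAS2 and CD274 fell as well, with changes from −1.79 to −2.68. All of these genes went the same way in 8 of 8 donors. In all 1998 genes passed, 929 up and 1069 down, of which 336 changed by over 1, and 3733 had an unadjusted p under 0.05. The count was 753 without control replicate 2, where ADAMTS6 (0.0639), CD274 (0.0687) and HAS2 (0.0611) no longer passed, and 1208 without control replicate 1.

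**Figure D1:**
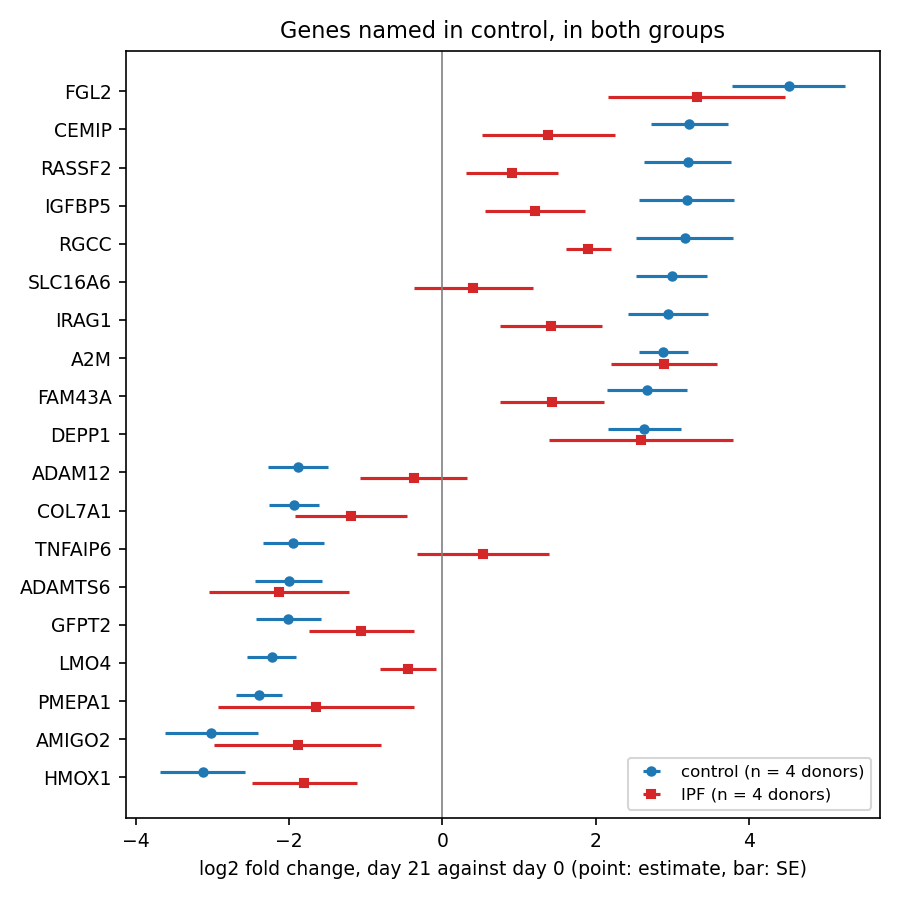
Change from day 0 to day 21 on the log2 scale (x axis) of 19 of the genes with the largest changes in control donors (y axis), in control and in IPF. Points are estimates from 4 donors and bars are standard errors; FGL2 stands at 4.52 and HMOX1 at −3.13 in control.

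Over all donors 7 lists passed. The p53 targets rose (camera adjusted p = 1.96e-04, and 0.881 with an estimated correlation), with 8 genes up over all genes and 10 adjusted over the list alone, among them ZMAT3 (0.81 ± 0.15), RRM2B (0.84 ± 0.20) and TP53INP1 (1.32 ± 0.32). Their mean rose in 7 of 8 donors and fell in control replicate 3 (−0.44), with an exact two-sided permutation p of 0.0313 (adjusted p = 0.156). The interferon response rose (adjusted p = 0.00153, and 0.351 with an estimated correlation), with 5 genes over all genes and 6 adjusted over the list alone, including XAF1 (1.19 ± 0.26) and IFI6 (1.34 ± 0.31). Its mean was higher at day 21 in 8 of 8 donors, by 0.71 ± 0.48 (SD), with an exact two-sided permutation p of 0.00781, the smallest that 8 donors allow (adjusted p = 0.0651 over 25 lists). Lung mesenchyme transcription factors rose (adjusted p = 0.0218, and 0.408 with an estimated correlation), with 4 genes up over all genes and 6 up and 1 down adjusted over the list alone. TBX4 (0.80 ± 0.18), FOXF1 (1.16 ± 0.30) and TCF21 (1.74), which pattern the embryonic lung, and the non-coding RNA FENDRR (2.01 ± 0.46) rose. This list was also higher in 8 of 8 donors, by 0.42 ± 0.23 (SD), with the same exact permutation p of 0.00781 (adjusted p = 0.0651), but its camera call was lost without IPF replicate 1 (0.0604).

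Among the lists that fell over all donors, TGF-beta response genes were negative in 16 of 17 cases (adjusted p = 0.00203, and 0.888 with an estimated correlation). PMEPA1 (−2.02), SMAD7 (−1.49 ± 0.33) and SKIL (−1.44 ± 0.35) were among those that fell, 4 genes over all genes and 8 adjusted over the list alone. The list mean fell in 6 of 8 donors (exact two-sided permutation p = 0.0313, adjusted p = 0.156) and rose in IPF replicates 1 (0.20) and 4 (0.06), and its change in IPF was −0.73 with all donors and −0.02 without replicate 3. All 20 DNA replication genes were negative (adjusted p = 0.00153, and 0.938 with an estimated correlation), and CDC6 (−1.10 ± 0.33) and FEN1 (−1.09 ± 0.36) fell, 2 genes over all genes and 0 adjusted over the list alone. All 20 mitosis genes were negative (adjusted p = 0.0157, and 0.938 with an estimated correlation), and the cell cycle regulator FOXM1 fell by 1.12 ± 0.38 (adjusted p = 0.0491), 1 gene over all genes and 0 adjusted over the list alone. That call was lost without control replicate 3 (0.0597) and without the day 21 library of IPF replicate 3 (0.0912). Cholesterol synthesis genes were negative in 19 of 20 cases (adjusted p = 0.0218, and 0.938 with an estimated correlation), and ACAT2 (−1.03 ± 0.24) fell over all genes and adjusted over the list alone. The cholesterol call was lost without control replicate 3 (0.135) or 4 (0.115) and without IPF replicate 1 (0.0822) or 2 (0.0688). The mean of the DNA replication list and that of the mitosis list each fell in 6 of 8 donors, with changes in IPF of −1.13 and −1.09, and of −0.33 and −0.09 without replicate 3. The cholesterol mean fell in 5 of 8 donors. The exact permutation p was 0.0781, 0.0859 and 0.125.

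Lists without a call over all donors held single genes that passed. In the matrix list (camera adjusted p = 0.669) DCN (2.23 ± 0.41), LAMA4 (1.02 ± 0.22) and LUM (1.62 ± 0.42) rose, 3 genes over all genes and 3 adjusted over the list alone, while COL1A1 (−0.23 ± 0.36) and COL3A1 (0.49 ± 0.48) did not pass (0.05 ± 0.27 and 0.85 ± 0.38 without the day 21 library of IPF replicate 3). FN1 had the highest value of all genes in each of the 16 libraries (19.81), so its change cannot be measured after quantile normalization. In the contractile list (0.254) MYLK, LMOD1 (1.92 ± 0.54), ACTG2 (2.06 ± 0.60) and MYL9 rose and TGFB1I1 and TNS1 fell, 4 up and 2 down both over all genes and adjusted over the list alone, while ACTA2 was at 0.83 ± 0.69 (adjusted p = 0.395, and 1.17 ± 0.66 without that library). Of the FGF, PDGF and IGF genes (0.0594) IGFBP4 (1.58 ± 0.23), IGFBP5 (2.20 ± 0.53) and FGFR1 (0.60 ± 0.16) rose, 3 over all genes and 5 adjusted over the list alone. The mean of this list was higher at day 21 in 8 of 8 donors, by 0.55 ± 0.28 (SD, exact permutation p = 0.00781, adjusted p = 0.0651). In the senescence list (0.593) the cell cycle inhibitor genes CDKN2A (1.60 ± 0.37) and CDKN2B (1.32) and IGFBP5 rose, 3 genes up and 1 down over all genes. In the hyaluronan list (0.866) the degrading gene CEMIP (2.31) rose with GPC6, and the synthase gene HAS2 fell with CEMIP2. Of the genes that make SSEA4 and SSEA1 (0.939), ST3GAL1 (−0.22 ± 0.25) and ST3GAL2 (−0.26 ± 0.12) did not pass and FUT4, a fucosyltransferase, fell by 0.42 ± 0.12 in 8 of 8 donors (adjusted p = 0.0228). S100A4 was at 0.14 ± 0.38 (adjusted p = 0.818) and MKI67, a marker of dividing cells, at −1.10 ± 0.69 (adjusted p = 0.260), and at −0.43 ± 0.35 without the day 21 library of IPF replicate 3.

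In the remaining lists over all donors, the adjusted p was 0.669 for Wnt, where SFRP1 (2.03), FZD7 (1.21) and DKK3 (0.64) rose and WNT5B (−0.83) fell, and 0.0927 for BMP, where BMPR2 (−0.40) and FSTL3 (−1.72) fell. It was 0.819 for the unfolded protein response, where the phosphatase subunit gene PPP1R15A (−0.43) fell, 0.646 for hypoxia, where ADM (1.64) and ALDOC (0.84) rose and ENO1 (−0.63) fell, and 0.792 for inflammatory cytokines, where CCL2 (2.07) and SOD2 (1.15) rose. Immediate early genes were at 0.819 with ZFP36 (1.17) and BTG2 (1.42) up and IER3 (−1.11) down. Lipid genes were at 0.792 with PPARG (2.17) and PNPLA2 (0.55) up and FABP5 (−0.98) down. Matrix proteases were at 0.819 with TIMP2 (0.48) up, stromal markers at 0.884 with ANPEP (−0.95) down, and pericyte markers at 0.884 with ACTG2 up and KCNJ8 (−1.02) down. Ribosomal proteins (0.274) and Notch (0.851) had 0 genes past the threshold in limma. In 9 lists fewer than 5 genes were tested. Of these, Hedgehog had 4 tested genes, pluripotency, histones and leukocytes 2 each, epithelium and mesothelium 1 each, and endothelium, erythroid cells and mitochondrially encoded genes 0. Among their members GLI2, a Hedgehog effector, fell by 0.97 ± 0.29 and MUC1 rose by 1.61 ± 0.29.

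The next question was whether the change over the culture differs between IPF and control donors. There 0 genes passed in limma, with 531 at an unadjusted p under 0.05 where chance gives 510. The genes named had the smallest p. The serine synthesis gene PSAT1 (Entrez 29968) went from 11.20 ± 0.54 to 10.07 ± 0.52 (SD, n = 4) in control and from 9.83 ± 0.24 to 11.66 ± 0.82 in IPF, a difference between the changes of 2.96 ± 0.52 (adjusted p = 0.237). The lipoprotein receptor gene VLDLR (Entrez 7436) had a difference of 2.25 ± 0.39 (adjusted p = 0.237), and the proline synthesis gene PYCR1, the chaperone gene DNAJC1 and CISD2 had 1.64 ± 0.35, 1.23 ± 0.26 and 0.84 ± 0.18 (adjusted p = 0.546 for each). On the other side were CYFIP1 (−0.63 ± 0.14, adjusted p = 0.587), and MAPKBP1 (−0.68 ± 0.16), PRKCD (−1.32 ± 0.32), CTNNA1 (−0.56 ± 0.14) and SPOCD1 (−0.99 ± 0.24), each with an adjusted p of 0.590. S100A4 was at −1.72 ± 0.66 (adjusted p = 0.870) and MKI67 at −1.09 ± 1.40 (adjusted p = 0.991), and at 0.27 ± 0.72 without the day 21 library of IPF replicate 3. COL1A1 (0.37 ± 0.73), COL3A1 (0.85 ± 0.97), ACTA2 (0.46 ± 1.42), ST3GAL1 (0.14 ± 0.51) and ST3GAL2 (−0.32 ± 0.24) did not pass. Without the day 21 library of IPF replicate 3 they were at 1.00 ± 0.48, 1.69 ± 0.66, 1.23 ± 1.32, 0.34 ± 0.51 and −0.15 ± 0.20 in the same order, and none passed.

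The unfolded protein response was the 1 list past the threshold in this comparison (camera adjusted p = 1.34e-15, 1.61e-13 with the donor as a block and 0.635 with an estimated correlation). The number of lists was 7 without the day 21 library of IPF replicate 3 and 4 under cyclic loess normalization. It was 8 without IPF replicate 3, 5 without IPF replicate 2 or control replicate 4, 3 without IPF replicate 1 and 2 without control replicate 1 or 2. The difference was positive for 19 of 20 members with a median of 1.28, and 0 members passed over all genes against 8 adjusted over the list alone. Among them were XBP1 (1.25 ± 0.30), ASNS (2.49 ± 0.61) and DNAJB9 (1.84 ± 0.57). The list mean changed by −0.60 ± 0.46 in control and by 0.70 ± 1.01 in IPF (SD, n = 4 donors each), where replicate 2 fell by 0.31 and the mean without replicate 3 was 0.24. The difference of 1.30 had an exact two-sided permutation p of 0.0571 (adjusted p = 0.714 over 25 lists), and without IPF replicate 3 it was 0.84 (exact permutation p = 0.114). The day 21 library of that replicate had a list mean of 14.11 against 12.25 to 12.47 in the other IPF day 21 libraries. The matrix, TGF-beta and inflammatory lists came next, each with an adjusted p of 0.0726. The matrix list had a difference of 0.41 between the donors' changes, and of 0.97 without IPF replicate 3 (exact permutation p = 0.0571). The TGF-beta list had an exact permutation p of 0.371 with all donors and of 0.0286, the smallest for 3 against 4 donors, without IPF replicate 3. Stromal markers changed by 0.098 ± 0.085 in control and by −0.195 ± 0.048 in IPF, with an exact two-sided permutation p of 0.0286, the smallest for 4 against 4 donors (adjusted p = 0.714).

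**Figure D2:**
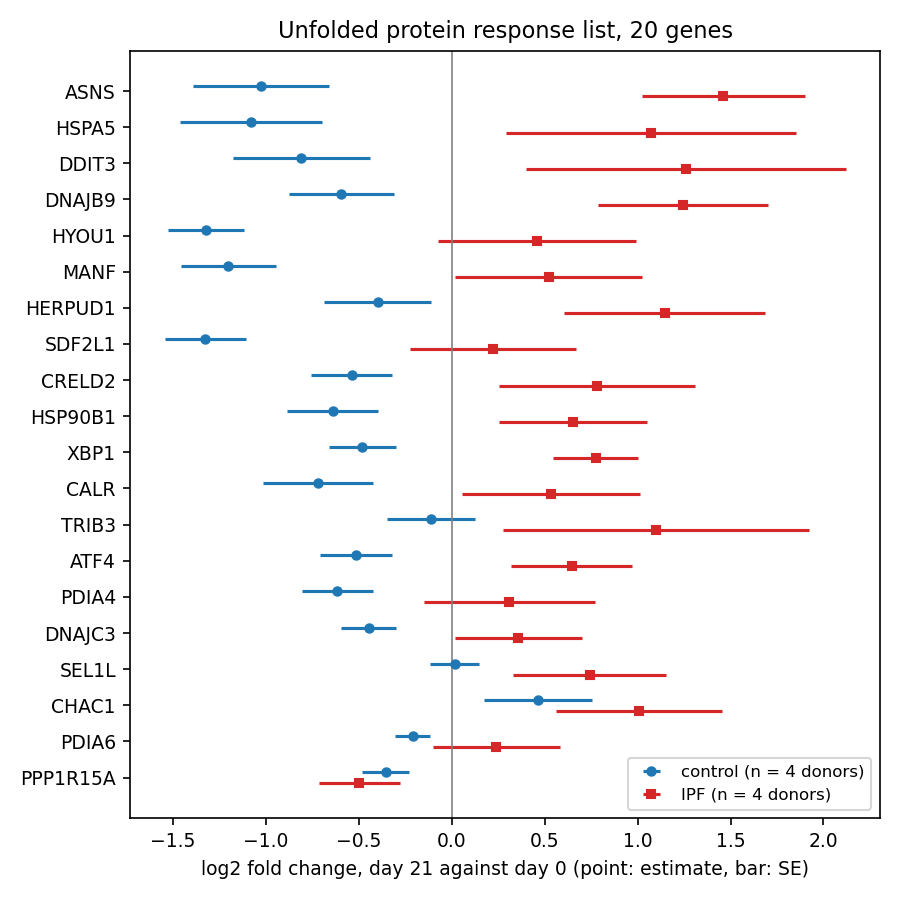
Change from day 0 to day 21 on the log2 scale (x axis) of the 20 unfolded protein response genes (y axis) in control and in IPF. Points are estimates from 4 donors and bars are standard errors; ASNS stands at 1.46 in IPF, and 18 of 20 genes are negative in control and 19 of 20 positive in IPF.

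**Figure D3:**
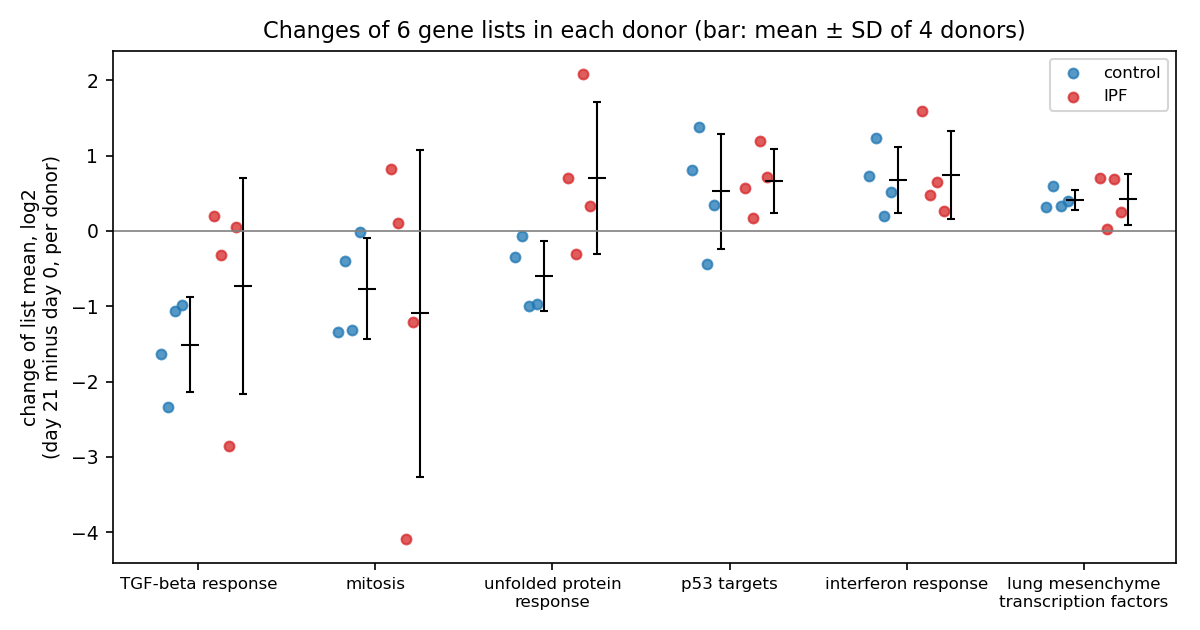
Change of the mean log2 value of 6 gene lists from day 0 to day 21 in each donor (points), with the mean and SD of 4 donors (bars), in control and in IPF. The interferon and lung mesenchyme lists are above 0 in 8 of 8 donors.

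The freshly sorted cells of IPF and control donors were compared at day 0, where the question is whether the founding cells already differ. No gene passed in limma (0 of 10209, smallest adjusted p = 0.263), and 1000 had an unadjusted p under 0.05, 467 up and 533 down, where chance gives 510. The smallest p values belonged to the efflux pump gene ABCC4 (Entrez 10257), at 1.00 ± 0.13, USP53 (1.11 ± 0.15), the transmembrane collagen gene COL13A1 (1.35 ± 0.21), MYO6 (0.79 ± 0.12) and NABP1 (1.14 ± 0.18), each with an adjusted p of 0.263. In the other direction were TENM4 (−1.15 ± 0.19, adjusted p = 0.263) and, with an adjusted p of 0.351, PSAT1 (−1.38 ± 0.26), PYCR1 (−1.03 ± 0.19), HNRNPC (−0.52 ± 0.10) and the translation regulator gene EIF4EBP1 (−0.55 ± 0.11). S100A4, a calcium-binding protein gene of motile fibroblasts, was at 1.75 ± 0.53 (n = 4 donors per group, adjusted p = 0.415). ST3GAL1 (0.27 ± 0.31) and ST3GAL2 (0.13 ± 0.15), which make SSEA4, COL1A1 (−0.34 ± 0.25), COL3A1 (−0.52 ± 0.45), ACTA2 (−0.39 ± 0.83) and MKI67 (−0.03 ± 0.32) did not pass.

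Of the lists at day 0, all 24 ribosomal protein genes were lower in IPF (camera adjusted p = 1.63e-08, and 0.887 with an estimated correlation) with a median of −0.24, among them RPS2 (−0.46 ± 0.15) and RPLP2 (−0.27). The donors' list means differed by −0.24 (exact two-sided permutation p = 0.0286, adjusted p = 0.357). All 20 mitosis genes were lower (adjusted p = 3.74e-06, and 0.887 with an estimated correlation), and BIRC5, an inhibitor of apoptosis that acts in cell division, was at −0.61 ± 0.14, 1 gene adjusted over the list alone against 0 over all genes. Both of these camera calls held with each donor left out. The donors' means of the mitosis list differed by −0.42, with an exact permutation p of 0.171 (adjusted p = 0.714). TGF-beta response genes (all 17 lower, adjusted p = 0.0125, and 0.887 with an estimated correlation) had PMEPA1 at −1.43 ± 0.88, and the call was lost without control replicate 4 (0.0702) or IPF replicate 4 (0.251). DNA replication (19 of 20 lower) and p53 targets (15 of 17 higher) each had an adjusted p of 0.0183, and 0.914 with an estimated correlation, with RFC4 at −0.50, GDF15 at 1.87 ± 0.70 and ZMAT3 at 0.40. The replication call was lost without control replicate 1 (0.126), 2 (0.0524) or 4 (0.0792) or IPF replicate 2 (0.642) or 4 (0.146), and the p53 call without control replicate 2 (0.539) or 4 (0.0792) or IPF replicate 4 (0.146). Unfolded protein response genes were lower in 16 of 20 cases (adjusted p = 0.0231, and 0.914 with an estimated correlation), with ASNS at −1.20 ± 0.34 and XBP1 at −0.55 ± 0.19, and the call was lost without control replicate 3 (0.103) or 4 (0.140) or IPF replicate 1 (0.578). In these last 4 lists 0 members passed limma over all genes or adjusted over the list alone. Between the donors' means the exact permutation p was 0.114 for TGF-beta (adjusted p = 0.571) and 0.429 for DNA replication (adjusted p = 0.893). It was 0.314 for p53 targets (adjusted p = 0.786) and 0.257 for the unfolded protein response (adjusted p = 0.714). The FGF, PDGF and IGF list differed by 0.31 between the donors' means (exact permutation p = 0.0286, adjusted p = 0.357) without a camera call (0.507). Of 6 lists past the threshold with all donors, 2 were left without control replicate 4 and 3 without IPF replicate 4. In lists without a call CCL2 (1.27), CEMIP (2.99), A4GALT (0.84) and NOTCH1 (0.61) were higher and CXCL12 (−1.31), FABP5 (−1.10), MCAM (−1.32) and DES (−2.60 ± 0.82) lower adjusted over the list alone, and not over all genes.

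The progeny were compared in the same way at day 21. No gene passed in limma (0 of 10209, smallest adjusted p = 0.188), and 766 had an unadjusted p under 0.05, 392 up and 374 down. GABARAPL1 was at 1.77 ± 0.24 (adjusted p = 0.188), VLDLR at 1.90 ± 0.32 and DNAJC1 at 0.99 ± 0.17 (adjusted p = 0.306 for both), GASK1B, a Golgi kinase family gene, at 2.20 ± 0.39 (adjusted p = 0.330) and CHAC1, a glutathione-degrading gene of the unfolded protein response, at 1.46 ± 0.28 (adjusted p = 0.415). In the other direction the mesenchymal transcription factor gene FOXC2 (Entrez 2303) was at −2.23 ± 0.29 and TRIM55 (Entrez 84675) at −2.49 ± 0.34 (adjusted p = 0.188 for both), ARHGAP22 at −1.41 ± 0.20 (adjusted p = 0.203), SEMA3F at −1.53 ± 0.23 (adjusted p = 0.253) and RGS4 at −1.81 ± 0.30 (adjusted p = 0.306). Without control replicate 4, TRIM55 passed (0.0161). COL1A1 (0.03 ± 0.64), COL3A1 (0.34 ± 0.78), ACTA2 (0.07 ± 1.01), S100A4 (0.03 ± 0.30), ST3GAL1 (0.41 ± 0.36), ST3GAL2 (−0.19 ± 0.18) and MKI67 (−1.13 ± 1.25) did not pass. Without IPF replicate 3 they were at 0.66 ± 0.40, 1.17 ± 0.39, 0.84 ± 0.88, −0.03 ± 0.33, 0.61 ± 0.36, −0.02 ± 0.13 and 0.23 ± 0.60 in the same order, and none passed.

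At day 21 all 20 unfolded protein response genes were higher in IPF, with a median of 0.98 (camera adjusted p = 3.06e-12, and 0.727 with an estimated correlation). DNAJB9 was at 1.47 ± 0.41 and XBP1 at 0.71 ± 0.22, and CHAC1 was the 1 gene that passed adjusted over the list alone, against 0 over all genes. The donors' list means differed by 0.98, with an exact two-sided permutation p of 0.0286 (adjusted p = 0.179), and by 0.54 without IPF replicate 3 (exact permutation p = 0.0571). p53 targets were higher in 15 of 17 cases (adjusted p = 0.00298, and 0.815 with an estimated correlation), with CDKN1A, which halts the cell cycle, at 0.74 ± 0.26 and GDF15 at 2.46 ± 0.90. The donors' means of the p53 list differed by 0.45, and by 0.24 without IPF replicate 3 (exact permutation p = 0.514), where the list kept its call (adjusted p = 0.0293). All 20 DNA replication genes were lower (adjusted p = 0.00657, and 0.815 with an estimated correlation), with MCM2 at −0.91 ± 0.55, and this call was lost without IPF replicate 3 (0.742). In both lists 0 members passed limma over all genes or adjusted over the list alone. These 3 lists were those past the threshold with all donors. The number was 14 without IPF replicate 3, 7 without control replicate 4 and 6 without control replicate 3 or IPF replicate 2 or 4. Stromal markers (−0.29), the Wnt list (−0.28) and the SSEA synthesis list (0.18) had an exact permutation p of 0.0286 between the donors' means (adjusted p = 0.179) and no camera call (0.0846, 0.552 and 0.0664). Without IPF replicate 3 the matrix list (0.24 with all donors, 0.61 without), senescence (0.40 and 0.69), inflammatory cytokines (0.81 and 1.29) and ribosomal proteins (−0.17 and −0.35) had an exact permutation p of 0.0286 as well, the smallest for 3 against 4 donors and not adjusted over the lists. Of single members in other lists LOX (1.86 ± 0.38, matrix), TNFAIP6 (2.19 ± 0.46, TGF-beta), MEIS2 (−1.16 ± 0.20, lung transcription factors), RBPJ (−1.01 ± 0.20, Notch), NT5E (−1.01 ± 0.27) and ANPEP (−1.26 ± 0.32, both stromal) and SDC4 (−0.56 ± 0.14, hyaluronan) passed adjusted over the list alone and not over all genes. The differences between IPF and control at day 0 and at day 21 had a Pearson's r of 0.361 across genes, and 9 of 35 splits of the donors gave an r as high (median of the splits 0.246).

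The first principal component carried 40.5% of the variance and the second 11.71%. On the first, control libraries were at −29.13 ± 11.64 at day 0 and 12.48 ± 13.94 at day 21, and IPF libraries at −14.67 ± 12.46 and 31.32 ± 40.82 (SD, n = 4). The days overlapped there, with IPF replicate 4 at −0.20 on day 0 and IPF replicate 1 at −3.86 and control replicate 4 at −2.49 on day 21. The day 21 library of IPF replicate 3 lay at 83.12 and that of replicate 4 at 44.67. On the second component the day 0 libraries ran from −1.58 to 22.33. The day 21 libraries ran from −26.66 to −6.92 there, except that of IPF replicate 3 at 36.56. The day 21 library of replicate 3 had a median correlation with the other libraries of 0.795, against 0.895 to 0.941 for the rest. Its mean over the mitosis genes was 7.49, against 10.65 to 13.05 in the other 15 libraries. The median standard deviation of a gene was 0.216 in control day 0, 0.225 in control day 21, 0.224 in IPF day 0 and 0.313 in IPF day 21.

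**Figure D4:**
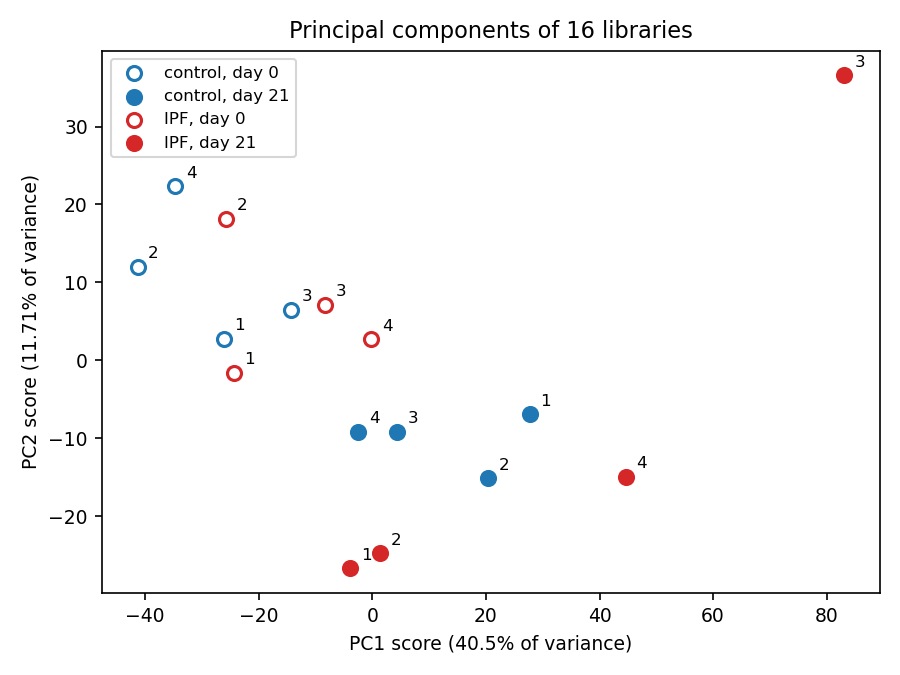
First (40.5% of the variance) against second (11.71%) principal component of the tested genes, in arbitrary units. Points are the 16 libraries, open at day 0 and filled at day 21, in blue for control and red for IPF, with the replicate number; the day 21 library of IPF replicate 3 lies at 83.12 on the first.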

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

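The tests of proliferation and of transcript length, and the test of a larger spread between IPF donors, were set before their results were seen, and the other tests in this part were chosen after the results they bear on had been seen, as were the 5 later gene lists.

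For the interaction of disease and day, 4 gene lists passed the threshold in camera at the preset correlation between genes. The unfolded protein response list had an adjusted p of 1.34e-15. Among the 5 lists written later, serine, one-carbon, proline and amino acid supply had 2.30e-13, translocation and glycosylation in the endoplasmic reticulum (ER) 4.48e-12, and small leucine-rich proteoglycans with elastic fibre proteins 0.00263. Vesicle coats (0.290) and complement (0.197) did not pass. With an estimated correlation the unfolded protein response had an adjusted p of 0.635 over 25 lists. Over the 5 later lists amino acid supply and ER translocation had 0.0348 each, and proteoglycans with elastic fibre proteins 0.0855. Between the donors' changes the exact permutation p was 0.0571 for the unfolded protein response (adjusted p = 0.714). Without adjustment it was 0.0286 for amino acid supply and for ER translocation, and 0.286 for proteoglycans with elastic fibre proteins. The unfolded protein response and the proteoglycan list thus passed neither with an estimated correlation nor between the donors' changes. The later lists were written from leading genes seen in these same donors, so their p values are no independent test of a difference.

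The unfolded protein response list had a lower mean at day 21 than at day 0 in control donors, among them HYOU1, SDF2L1 and MANF, and a higher mean in IPF donors other than replicate 2 (−0.31). The difference between the diseases was 1.30, and 1.18 with a standard error of 0.44 with the change of the mitosis list as a covariate. This does not decide on a difference in proliferation between donors. The mitosis list changed by −0.77 on average in control and −1.09 in IPF, so this covariate could move the difference only a little. IPF replicate 3, at −4.10 for mitosis and 2.08 for the unfolded protein response, also lay far from the other donors in both lists. An effect of the 1 outlying IPF library, the day 21 library of replicate 3, stays open. Without it the list kept its call at the preset correlation (adjusted p = 1.59e-10, and 6.66e-18 to 1.77e-09 over the 12 alternatives run). Without replicate 3 the change in IPF went from 0.70 to 0.24, and the difference between the diseases from 1.30 to 0.84, with an exact permutation p of 0.114. The disease of the donors as a biological difference stays open, with an exact two-sided permutation p of 0.0571 over the 8 donors, and it cannot be told apart from differences between these donors that the labels do not give. Handling of the cultures was not tested.

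The day 21 library of IPF replicate 3 lay far from the other libraries, with low mitosis genes and high unfolded protein response genes such as HYOU1 (14.66 against 13.00 to 13.09 in the other IPF day 21 libraries). Spearman's rho across genes of its deviation with transcript length was 0.15 (10100 genes, 98.93% of those tested). That of the others ran from −0.376 in control day 0 replicate 3 to 0.263 in IPF day 0 replicate 3. This argues against a bias by transcript length beyond that of the other libraries. RNA degradation stays open, since transcript length does not measure RNA integrity and the other libraries may be affected too. Fewer reads in this library stay open, since no depth is given in the sources used here and the number of distinct values after normalization, 5268 against 4461 to 6818 in the others, does not measure it. Cells of another type stay open, since the cells were sorted by SSEA4 and size before the culture and no sort after it is given in the labels: of 22 markers of other cell types 1, the pericyte gene ABCC9 (12.65 against 12.64 in the next library), was highest in this library where 1.38 are expected, and 1 of 5 marker lists had its highest mean there. No biological explanation was tested for this library.

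Many more genes passed over the culture in control (257) than in IPF (3), with 907 and 37 under sample weights. A larger spread between IPF donors may account for this, since the IPF changes with the standard errors of control gave 1515 genes and the control changes with the standard errors of IPF gave 12. The first of these counts also holds noise, since the IPF changes are the less precise ones. For the control genes as a set, changes that go another way in IPF are argued against. Of these genes 93%, FGL2 and HMOX1 among them, had the same sign in IPF against 74.62% of all genes. An unadjusted p under 0.05 with that sign was found in IPF for 118 of the 257. Single genes did go the other way, such as TNFAIP6, which fell in control and had IPF means of 9.20 at day 0 and 9.74 at day 21. So did the mean of the unfolded protein response list (−0.60 in control and 0.70 in IPF). The median standard error was 0.201 in IPF and 0.162 in control. A biological difference between the diseases in the spread itself stays open, and leaving out control replicate 2 alone removed all 257 calls, with A2M at 2.62 against 2.88.

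Other splits of the libraries into groups of the same size were compared with the real ones. For IPF against control 5 of 35 splits at day 0 gave as many genes at an unadjusted p under 0.05 as the real 1000 (highest other 1592), and 7 of 35 at day 21 gave as many as the real 766 (highest other 2142), so chance cannot be excluded for these counts. For the interaction 7 of 35 gave as many as the real 531 (highest other 1093), and chance cannot be excluded there either. Some groupings other than disease thus gave more genes than the real ones, 2142 against 766 at day 21. What sets those splits apart was not tested. For day 21 against day 0 in control 1 of 35 splits, the real one, gave 257 genes (highest other 0). Over all donors 1 of 100 drawn splits, the real one, gave 1998 genes (highest other 11). Many of these splits put both libraries of a donor in 1 group and ignore the pairing, so they cannot by themselves exclude chance. In IPF 1 of 35 splits, the real one, gave 3 genes, while another gave 1. The count was 0 without replicate 1, 3 or 4, with changes of similar size (GABARAPL1 at 2.54 to 2.73 with 1 donor left out). The 8 splits that part all donor pairs within control or within IPF are too few for a share under 0.05 (highest other 0 and 1). With the pairing kept, chance therefore cannot be excluded for the counts in control or in IPF. Among 100 splits that part all donor pairs only the real one gave 1998 genes over all donors, and the highest other count was 1170. Each of these splits exchanges the days of some donors and keeps those of the rest, so it holds part of the day effect.

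In 52 of 708 groups of 4 values, 1 library lay far from the other 3 by Dixon's test, which is past for about 1 in 20 groups by chance (35.4 expected). The ratios of gap to range are given for most of them. In IPF day 21, 19 groups were past and replicate 3 made 14 of them, with ratios from 0.833 to 0.943. In that replicate the ratio was 0.899 for COL3A1 (13.28 against 16.44 to 16.80) and 0.883 for HAS2 (9.17 against 12.68 to 13.14), which were low. It was 0.863 for ID3 (8.34 against 12.47 to 13.13) and 0.880 for ID4 (5.76 against 8.56 to 8.94), which were low too. Among high values it was 0.943 for HYOU1, 0.844 for MANF, 0.898 for XBP1, 0.904 for CANX, 0.887 for GPT2 and 0.838 for LTBP3. It was 0.877 for the mean of the unfolded protein response list (14.11 against 12.25 to 12.47) and 0.849 for that of the cholesterol list, both high. In replicate 2 it was 0.852 for GABARAPL1, 0.839 for SPOCD1, 0.923 for BDKRB2 and 0.848 for ALDH1A1, and in replicate 1 it was 0.947 for the SSEA synthesis list.

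In IPF day 0 the ratio was 0.942 for ST3GAL2, 0.884 for EFEMP2, 0.944 for FAS, 0.840 for LMOD1 and 0.846 for the hyaluronan list in replicate 2. It was 0.866 for MKI67 in replicate 1, and 0.897 for LMO4 and 0.832 for CCNA2 in replicate 4. In replicate 3 it was 0.845 for FENDRR, 0.853 for RPL10A, 0.841 for TBX4 and 0.835 for the cholesterol list.

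In control day 0 replicate 3 had ratios of 0.885 for COL1A1 and also for FAM43A, 0.874 for PLTP, 0.890 for BIRC5, 0.868 for POLE2, 0.943 for RFC4, 0.937 for UHRF1, 0.840 for the DNA replication list and 0.940 for the hyaluronan list. Replicate 2 had 0.934 for USP53, 0.931 for PYCR1 and 0.871 for FAS, and replicate 1 had 0.903 for COL14A1. In control day 21 the ratio was 0.877 for HNRNPC and 0.863 for PRKCD in replicate 2, 0.920 for GASK1B, 0.909 for APOE and 0.830 for CFB in replicate 4, 0.849 for POLE2 in replicate 1 and 0.935 for XBP1 in replicate 3.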

How the results depend on the processing

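The comparison over all donors, cyclic loess normalization and leaving out the day 21 library of IPF replicate 3 alone were chosen after seeing the data. No direction of a gene named by size or smallest p, or of a called list among the 25, reversed under the alternatives run. Genes followed in every comparison other than FN1 did, and none passed the threshold in any alternative. Each gene combined with each alternative, the sign turned in 9 combinations and held in 103 at day 0, turned in 17 and held in 102 at day 21, and turned in 3 and held in 74 in control. It turned in 7 and held in 77 in IPF, turned in 7 and held in 112 for the interaction, and turned in 5 and held in 107 over all donors. COL1A1 over all donors went from −0.23 to 0.05 without the outlying library alone. For genes named by size or smallest p, each combined with each alternative, the side of the threshold was kept in 312 of the combinations over all donors and lost in 4. It was kept in 141 and lost in 73 in control, kept in 93, lost in 17 and gained in 9 in IPF, and kept in 169 for the interaction and 160 for IPF against control at day 0. At day 21 it was kept in 165 and gained in 1, by TRIM55.

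In control, 907 genes passed with sample weights, 135 with a log2 fold change over 1 and 586 with the donor as a block; leaving out each donor gave 0 to 433. In IPF, 5 passed with the stricter filter, where DOCK10 and PLTP joined the 3 genes, as fewer genes were tested. There were 37 with sample weights, which gave the outlying library less weight, 0 without that library, and 0 to 2 with each donor left out. Over all donors 336 changed by over 1, and leaving out each donor gave 753 to 2033. At day 0, 1 gene passed with no filter, NCKAP5, and leaving out each donor gave 0 to 2, with FLRT2 and RND3 passing without IPF replicate 3. At day 21 leaving out each donor gave 0 to 1. The genes NCKAP5, FLRT2 and RND3 were named after their values were seen, and the cause was not tested. The interaction gave 0 genes in limma under every alternative run, with 328 to 787 at an unadjusted p under 0.05 when each donor was left out. With the 2 series of sample names as a covariate 0 genes passed at day 0 (888 at an unadjusted p under 0.05), at day 21 (580) and for the interaction (585).

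The donor as a block changed no call of a comparison's named genes or lists other than those printed beside the results, except that the control lists of FGF, PDGF and IGF genes and of the Wnt pathway then passed (adjusted p = 0.0462 for both). With an estimated correlation in camera 0 of the 25 lists passed in each of the 6 comparisons. With each donor left out the number of lists past the threshold ran from 2 to 8 at day 0 (6 with all donors), 3 to 14 at day 21 (3), 7 to 11 in control (10), 5 to 8 in IPF (5), 1 to 8 for the interaction (1) and 5 to 9 over all donors (7). At day 21 it was 5 with quantile normalization repeated and 14 without the outlying library. For the interaction it was 4 with cyclic loess normalization and 7 without that library. The cause was not tested. Depth is unknown, so its limit on the calls cannot be given.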

Other observations

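The tests in this part were all chosen after the leading genes had been seen. The lists were tested without the genes that led to them, except ASNS and CHAC1. The list of proteoglycans and elastic fibre proteins also kept LUM, BGN, ELN, FBN1 and LTBP2, which had been tested in earlier lists.

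Complement genes, whose products tag and lyse targets in serum and tissue, rose over the culture as a list in IPF (camera adjusted p = 3.24e-04, and 0.0300 with an estimated correlation) and in control (7.86e-04, and 0.161 with an estimated correlation). Over all donors C1R rose by 1.95 ± 0.27 and C1S, its partner protease, by 2.03 ± 0.24 (adjusted p = 0.00141 and 6.67e-04, n = 8 donors), and both led to the list. Of 9 other members 7 rose, among them CFB (1.78 ± 0.43), C1RL (1.08 ± 0.19), SERPING1 (1.40), CD46 (0.58), C1QTNF1 (1.41 ± 0.38) and C4B (1.72 ± 0.25), whose reads a near-identical paralog can share. CD55 (0.07) and CD59 (−0.24) did not pass. The list had a camera adjusted p of 2.21e-04 over 5 lists, and of 0.00501 with an estimated correlation. Its mean rose in 8 of 8 donors by 0.97 ± 0.35 (SD). The exact two-sided permutation p was 0.00781, the smallest that 8 donors allow and not adjusted over the 5 lists.

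Small leucine-rich proteoglycans and elastic fibre proteins, which space collagen fibrils and build microfibrils, also rose as a list over all donors (camera adjusted p = 0.0388, and 0.382 with an estimated correlation). PRELP (2.29 ± 0.38), LTBP4 (2.14 ± 0.25), TNXB (2.50 ± 0.60) and MFAP4 (2.16 ± 0.52) led to the list. Of its 15 other genes LUM, EFEMP1 (1.45 ± 0.34), EFEMP2 (0.58 ± 0.12) and LTBP3 (0.80 ± 0.15) rose and 11 did not pass, among them ELN (−0.87 ± 1.07), which encodes elastin, and FBN1 (−0.36 ± 0.22). The donors' mean change was 0.42 ± 0.65 (SD, 6 of 8 up, exact permutation p = 0.117). Of the other lists over all donors, vesicle coats, amino acid supply and ER translocation did not pass (adjusted p = 0.785, 0.785 and 0.908).

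Amino acid supply and secretory genes may move as a group by disease over the culture. The amino acid list is broader than its name, since it also holds AARS1, WARS1, GARS1, SARS1, EPRS1, DDIT4 and CHAC1. VLDLR, the lipoprotein receptor gene, was among the genes that led to it. The list of serine, one-carbon, proline and amino acid supply changed by −0.45 ± 0.24 in control and by 0.54 ± 0.55 in IPF (SD, n = 4), and that of ER translocation and glycosylation by −0.23 ± 0.17 and 0.16 ± 0.13. For both the exact two-sided permutation p was 0.0286, the smallest for 4 against 4 donors and not adjusted over the 5 lists. The leading genes were seen in these same donors, and the members kept were picked as related to them. These p values are therefore no independent test of the hypothesis. Members of the first were PHGDH (1.54 ± 0.46), GPT2 (0.80 ± 0.22) and ASNS (2.49 ± 0.61), as differences between the changes, and of the second ALG5 (0.83 ± 0.24), SSR1 (0.65 ± 0.21) and CANX (1.02 ± 0.32), none past the threshold in limma. Without IPF replicate 3 the difference between the changes went from 0.99 to 0.73 for the first list (exact permutation p = 0.0571) and from 0.38 to 0.37 for the second (0.0286). ASNS and CHAC1 are in both the amino acid and the unfolded protein response lists and had been seen there. Without them the first list changed by −0.47 in control and by 0.47 in IPF, with an exact permutation p of 0.0286 with all donors and also without IPF replicate 3. At day 0 both lists were lower in IPF (camera adjusted p = 5.30e-04 and 0.00937, and 0.264 and 0.394 with an estimated correlation) and at day 21 higher (1.70e-07 and 1.77e-06, and 0.121 and 0.109 with an estimated correlation). For proteoglycans and elastic fibres the exact permutation p was 0.286 with all donors and 0.0286 without IPF replicate 3, and for complement and vesicle coats it was 0.486 and 0.400.

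A load of secreted matrix might raise the unfolded protein response. Over the 8 donors the change of that list and the change of the matrix list had a Pearson's r of −0.390 (permutation p = 0.345) and a Spearman's rho of 0.0476 (permutation p = 0.935), and r was 0.660 without the 2 donors farthest from the median matrix change. Those donors were IPF replicates 2 and 3. The IPF replicates kept, 1 and 4, lay above all control donors in the matrix list (0.84 and 0.71) and in the unfolded protein response list (0.71 and 0.33). That r therefore also holds the gap between the diseases. A relation within a disease was not tested. The relation is left open, since its sign rests on the donors left out and r pools both diseases.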
